A study of Mus musculus with 4 samples.

How the data were processed

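Single-cell gene expression was measured in 4 mouse libraries, 1 in each of the groups IgG, Ac, C and aC+C. Per the labels' protocols, cells were captured in droplets with 10x Genomics single cell 3' reagents of version v2; the series' design text gives a target of about 5000 cells per sample. Per the submitters' processing notes, reads were processed with Cell Ranger 2.1.1 against the mouse genome build mm10, whereas the matrix headers name software version 3.0.2. The gene annotation release and the read alignment settings are not given in the sources used here. The deposited matrices hold raw UMI counts per gene and barcode, with no normalization, and the deposited lists of barcodes and of genes (other: names, not values) give the columns and rows of each matrix. Each library listed the same 6794880 barcodes and 27998 genes, so the matrices were not filtered for cells; this was checked on the values. That number of barcodes is the size of the list for the later v3 reagents, which conflicts with the v2 of the labels. UMI counts correct for duplicates made in amplification, but a transcript of a free molecule in the fluid is counted with those of the cell in the droplet. Reads that fall equally on near-identical genes may be assigned to either or to neither, which bears on genes such as Gm10073 and Gm10076.

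Total UMIs were 61519049 in IgG, 65973242 in Ac, 75665201 in C and 75067320 in aC+C. Barcodes of 1 to 50 UMIs, taken as background, held 4.99%, 4.62%, 4.34% and 3.58% of them. A barcode was called a cell if its total was at least 10% of the 99th percentile of the 5000 barcodes with the most UMIs, a rule of early Cell Ranger versions, if at least 200 genes had a UMI and if at most 10% of its UMIs came from mitochondrially encoded genes. The threshold was 7962 UMIs in IgG, 8520 in Ac, 8594 in C and 9280 in aC+C, with 2308, 2472, 2570 and 2360 barcodes at or over it. The mitochondrial maximum removed 18, 17, 52 and 14 of these, and the gene minimum 1 of Ac. Doublet scores were computed with the Scrublet function of scanpy 1.11.5, and in each library the cells with the highest scores were removed, 0.8% per 1000 cells, which came to 42, 48, 51 and 44 cells. Median genes per cell were 3633.5 in IgG, 3500.5 in Ac, 3734 in C and 3725.5 in aC+C.

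Counts were scaled to 10000 per cell and transformed as the natural logarithm of 1 plus the value. The 2000 most variable genes, picked per library and combined, leaving out variable segments of T cell receptors and immunoglobulins and mitochondrial and ribosomal protein genes, gave 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). No integration across libraries was done, since library and group are the same. Clusters were named from fixed lists of marker genes by the mean log2 fold of each list's genes in the cluster over the others, on CPM (UMIs of a gene per 1000000 UMIs) with an offset of 20. T cell clusters had Cd3d, Cd3e and Cd3g in on average at least 50% of cells and a T cell score of at least 0.3. They were called CD8 T-like if at least 80% of cells had each of Cd8a, Cd8b1 and Cd3e and at most 20% had Cd4 or Foxp3. Other classes needed a score of at least 0.5, or 1 where at least 50% of cells had Cd3e. Clusters with fewer than 3 detected markers, or with more markers of another type than their own among the 10 leading genes, were left unnamed. All these thresholds for naming, among them the percentages of cells with a gene and the score minimums, were set after the data were seen. So were the offset and the number of leading genes. The choice of the CD8 T-like, monocyte or macrophage-like and NK-like shares as the main shares was also made after the shares were seen. CD8 T-like cells were clustered again on their own at resolution 1 into sub-clusters. Of 606 genes in the lists and markers, 586 were found under the listed symbol, 3 under another symbol by gene ID, and 17 were not in the files.

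UMIs were summed over the cells of a class in each library and scaled to CPM of the class total, and Ac, C and aC+C were each compared with IgG, and aC+C with Ac and with C, as a ratio. With 1 library per group no test was possible. Intervals are exact Poisson intervals for a level, exact conditional binomial intervals for a ratio and Clopper-Pearson intervals for a share, all at 95% and for counting error only; molecules of 1 cell are not independent, and 1 cell can hold much of a gene's UMIs. Ratios against 0 UMIs were computed against a floor of 3 counts over the class. Genes with at least 100 UMIs over both libraries were ranked, and genes at least 2 times higher or lower were counted. Other classes were compared where both libraries had at least 100 cells. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, with the share in monocyte or macrophage-like cells as background, or in NK-like cells for Cd274.

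The following 26 lists of genes were used: cytotoxic effectors, exhaustion and inhibitory receptors, naive, memory and stem-like, tissue residency, T cell activation and costimulation, cytokines and chemokines of T cells, type I interferon response, interferon gamma response and MHC class I, MHC class II, S phase, G2 and M phase, glycolysis, hypoxia, oxidative phosphorylation, cholesterol biosynthesis, unfolded protein response, amino acid response, immediate early and dissociation genes, heat shock, TNF and NF-kB response, TGF-beta response, p53 response, inflammatory macrophage, alternative macrophage, ribosomal proteins and mitochondrially encoded. Several genes stand in more than 1 list, such as Xcl1, Ccl3, Ccl4, Ccl5, Tnf and Nr4a1. A list was described by the median ratio of its members with at least 20 UMIs, if at least 5 were measured, by the members at least 1.5 times higher or lower, and by the percentile of its median among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test between groups.

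Named genes followed a rule. For each comparison of CD8 T-like cells with IgG they are the 10 highest and 10 lowest genes, ranked by the interval bound nearest to 1 among genes with a ratio of at least 1.5 either way, leaving out mitochondrial, ribosomal protein (Rps, Rpl), T cell receptor, immunoglobulin and haemoglobin genes. For the other comparisons and classes they are the 5 highest and 5 lowest. Added to these are Cd8a, Cd8b1, Cd4, Cd3e, Ptprc, Muc2, Epcam, Pdcd1, Ctla4, Havcr2, Lag3, Tigit, Tox, Tcf7, Gzmb, Prf1, Ifng, Mki67 and Cd274, and for each list up to 4 members with at least 100 UMIs and the ratio farthest from 1. For CD8 T-like cells the text gives the highest and lowest genes, apart from 1 that is not reported here, and the fixed genes against IgG. Of the genes the rule picks for other classes and for the lists it gives only a part, which was chosen after their values were seen. The comparisons, lists, cell calling and this rule were fixed before the data were examined.

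The ratios and list medians were tested on simulated data in which 200 genes of a comparison were changed by set folds. All genes changed 3-fold or 5-fold were called at the 2-fold threshold. Of the genes changed exactly 2-fold, which lie at that threshold, 44% were called for Ac against IgG, 40% for C against IgG, 48% for aC+C against IgG, 36% for aC+C against Ac and 42% for aC+C against C. Intervals of unchanged genes held the true ratio for 95.4%, 94.7%, 95.8%, 95.8% and 95.3% of genes. The simulated counts were Poisson draws, the model that the intervals assume, so values near 95% were built in. They say nothing of UMIs that gather in single cells. In the same order, 0, 1, 0, 2 and 2 of 26 lists had a median outside the middle 95% of random lists.

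Alternatives were cells of at least 500 or 1000 UMIs, a mitochondrial maximum of 5% or 20%, doublets kept, Leiden resolutions of 0.5 and 2, CD8 T-like cells taken by transcripts (cells of T cell clusters with a Cd8a or Cd8b1 UMI and no Cd4 UMI, which takes in regulatory T-like cells with Cd8a), totals scaled by TMM, totals without mitochondrial and ribosomal protein genes, the mean over cells of UMIs per 10000, removal of 5% background in the proportions of the barcodes of 1 to 50 UMIs, minimums of 30 and 300 UMIs per gene, and thinning to 2000 UMIs or none. Leaving out sub-clusters 8 and 11, or sub-cluster 6, was added after the data were seen. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9; TMM factors were computed in R 4.3.3 with edgeR 4.0.16. T cell receptor sequences and raw reads were not used here.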

Results

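Single-cell RNA sequencing of mouse cells was done with a droplet method in which each cell is captured with its own barcode and each transcript molecule is counted through a unique molecular identifier (UMI). The series holds 4 libraries, 1 in each of the groups IgG, Ac, C and aC+C; the labels do not spell these names out. The labels conflict on the cells: the titles name immune cells and CD8 T cells from tumors, while the cell type field and the protocol describe goblet cells, the mucus-secreting cells of the gut lining. The libraries held 61519049 UMIs in IgG, 65973242 in Ac, 75665201 in C and 75067320 in aC+C. After filtering, 2248 cells of IgG, 2406 of Ac, 2467 of C and 2302 of aC+C remained. Their medians were 16459, 15820, 17210 and 17469.5 UMIs per cell. The minimum for a cell differed by library, at 7962, 8520, 8594 and 9280 UMIs. The shares and ratios below therefore describe cells with many UMIs, unless another setting is named. With a minimum of 500 UMIs, 3410, 3972, 4185 and 4061 cells remained. With 1 library per group there were no replicates, so no difference could be set against a spread between replicates and no test was made. All intervals are exact 95% intervals that cover counting error only.

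Most cells carried transcripts of immune cells. Over all called cells of any class, Ptprc, which encodes the leukocyte protein CD45, had a UMI in 94.3% of IgG, 91.5% of Ac, 91.8% of C and 85.8% of aC+C. Muc2, which encodes the main mucin of goblet cells, had 2, 2, 2 and 3 UMIs in all, and Epcam, an adhesion gene of epithelial and some immune cells, had a UMI in 10.9%, 6.32%, 10.7% and 4.996% of cells. No cluster was led by markers of goblet or epithelial cells. Cells with monocyte or macrophage markers made up 14.1% of IgG (12.7 to 15.6), 30.4% of Ac (28.5 to 32.3), 25.9% of C (24.2 to 27.7) and 35.9% of aC+C (33.9 to 37.9). CD8 T-like cells, the cytotoxic T lymphocytes named in the series title, were 27.1% of IgG (25.3 to 29.0), 27.7% of Ac (25.9 to 29.6), 13.6% of C (12.3 to 14.99) and 26.1% of aC+C (24.3 to 27.95). NK-like cells, innate lymphocytes that kill without prior priming, were 18.8% of IgG (17.2 to 20.4), 14.0% of Ac (12.7 to 15.5), 17.3% of C (15.9 to 18.9) and 6.26% of aC+C (5.30 to 7.32).

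Smaller classes also differed in size. Regulatory T-like cells, marked by Foxp3, made up 7.25% of IgG, 4.66% of Ac, 7.05% of C and 3.56% of aC+C. With cells of at least 500 UMIs these shares were 7.24%, 9.49%, 9.18% and 6.18%, and at a Leiden resolution of 0.5 no cluster had this name. Of the cells in their clusters 11 and 20, 58.2% and 56.5% also had a Cd8a UMI. Migratory dendritic-like cells, which carry antigen to lymph nodes, were 4.85% of IgG, 1.87% of Ac, 2.23% of C and 1.17% of aC+C; at a mitochondrial maximum of 5% they were 1.45%, 1.76%, 0.794% and 1.05%, so the higher share in IgG was not seen there, and at a Leiden resolution of 0.5 the name was lost. Conventional dendritic type 2-like cells were 4.63%, 2.78%, 3.57% and 1.52% in the same order, and type 1-like cells 1.73%, 1.247%, 1.82% and 1.13%. Fibroblast-like cells were 3.83%, 4.28%, 7.22% and 5.52%. No cluster was named B-like, CD4 T-like or neutrophil-like, which sets no limit on such cells within other clusters. Of the monocyte or macrophage-like class, cluster 0 held 67 of 317 cells in IgG, 251 of 731 in Ac, 267 of 639 in C and 296 of 826 in aC+C, and cluster 1 held 103, 249, 178 and 204. Thresholds for naming that were set after the data were seen left 17.7% of IgG, 13.01% of Ac, 21.3% of C and 18.9% of aC+C unnamed. Among these, cluster 3, with a median of 70629 UMIs per cell, made up 3.25%, 5.49%, 6.45% and 13.5%. Cluster 9 made up 5.92%, 0.540%, 9.44% and 1.35%, cluster 10 made up 4.58%, 5.32%, 2.84% and 2.52%, and cluster 19 made up 3.96%, 1.66%, 2.55% and 1.48%.

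**Figure D1:**
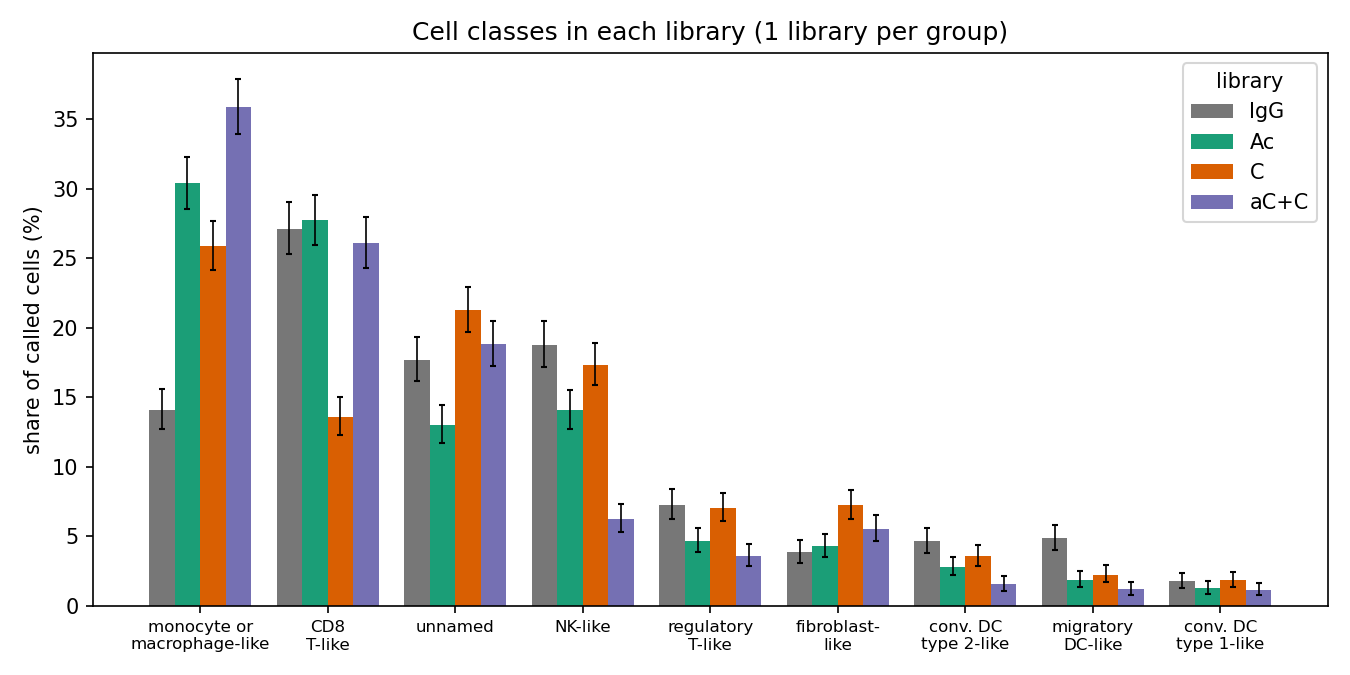
Share of called cells in each cell class (vertical axis, %) for each of the 4 libraries, with bars starting at 0 and exact 95% intervals for counting error (1 library per group; DC is dendritic cell, conv. is conventional). The monocyte or macrophage-like share was 14.1% in IgG and 35.9% in aC+C, the CD8 T-like share was 13.6% in C, and the NK-like share was 6.26% in aC+C.

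Expression was compared in the CD8 T-like class, with 610 cells of IgG, 667 of Ac, 335 of C and 601 of aC+C and 11303227, 11316247, 6201894 and 11703640 UMIs. Levels are in CPM, the UMIs of a gene per 1000000 UMIs of the class. Cluster 2 was its largest cluster in every library. With each cell thinned to 1000 UMIs, Cd8a (ENSMUSG00000053977), the alpha chain of the CD8 co-receptor, was seen in 54.1% of the class in IgG, 53.8% in Ac, 54.6% in C and 53.2% in aC+C. The background in monocyte or macrophage-like cells, which should lack it, was 0.946%, 0.410%, 0.313% and 0.121%. Before thinning, median depths in IgG, Ac, C and aC+C were 15359.5, 14303, 15371 and 17439 UMIs in the CD8 T-like class and 12089, 15629, 13917 and 14277 in the background class. Prf1 (ENSMUSG00000037202), which encodes the pore-forming protein perforin, was seen in 13.3%, 13.9%, 11.6% and 23.5% of thinned CD8 T-like cells, and the interval in aC+C was 20.1% to 27.1%; in the background class the shares were 0.631%, 0.410%, 0% and 0.242%. Pdcd1 (ENSMUSG00000026285), which encodes the inhibitory receptor PD-1, was seen in 29.0%, 30.3%, 18.8% and 33.9%, against 1.26%, 0.410%, 0.782% and 0.242% of the background class.

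Ac was first compared with IgG. In CD8 T-like cells, 24 of 8652 genes were at least 2 times higher in Ac and 12 at least 2 times lower. These counts were 17 and 26 at a Leiden resolution of 0.5, 18 and 20 with doublets kept, and 16 and 19 at a mitochondrial maximum of 20%, so which side held more genes depended on the processing. Ifitm2 (ENSMUSG00000060591), an interferon-induced transmembrane protein that restricts virus entry, was 2.40 times higher (2.26 to 2.56), with 296 against 123 CPM. Ccl5, a chemokine of effector T cells, was 1.52 times higher (1.48 to 1.55), and Cd160, a receptor of activated cytotoxic cells, 1.68 times (1.55 to 1.81). Ifitm2 and Ccl5 are among the leading genes of sub-cluster 6, which held 148 of 667 cells of Ac and 8 of 610 of IgG. Their ratios therefore do not separate a change across the class from a change in its make-up. Prf1 was 1.37 times higher (1.28 to 1.46), while Gzmb, which encodes granzyme B, had a ratio of 1.05 and Cd8a one of 1.02 (0.988 to 1.05). Among the lowest genes was Klra3 (ENSMUSG00000067591), an NK cell receptor of the Ly49 family, with a ratio of 0.0621 (0.0384 to 0.0955). Others were Klrb1b at 0.191, Ncr1 at 0.225, Tyrobp at 0.415 and Fcer1g at 0.479. Fcer1g is a leading gene of sub-cluster 1, which made up 11.5% of the class in Ac and 22.3% in IgG. Sub-cluster 8, led by NK cell genes, made up 2.70% of the class in Ac and 8.03% in IgG; without sub-clusters 8 and 11, a setting chosen after seeing the data, Klra3 had a ratio of 0.0410 and Tyrobp one of 0.941. Tcf7 (ENSMUSG00000000782), the transcription factor of naive and stem-like T cells, had a ratio of 0.408 (0.272 to 0.601), with 3.36 against 8.23 CPM, and Lef1, its relative, one of 1.69 (1.37 to 2.08).

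Other genes at the extremes of Ac against IgG had lower counts. Apobec2 was 5.08 times higher (3.26 to 8.23), Upk1a 3.75 times, Fam20a 3.34 times, Cdh1, which encodes the adhesion protein E-cadherin, 2.94 times, Fam178b 2.71 times and Apoe, a lipid carrier abundant in macrophages, 2.44 times. The chemokine genes Ccl1 and Cxcl2 were 3.96 and 3.68 times higher, with 50% of the IgG UMIs of Ccl1 and 39.7% of the Ac UMIs of Cxcl2 in 1 cell. Cd81 was 3.41 times higher, with 32.9% of its Ac UMIs in 1 cell, but 0.768 times as high when cells of at least 500 UMIs were taken and 0.938 times at a Leiden resolution of 0.5. Ly6k, Krtcap3 and Tmem176b had ratios of 0.162, 0.268 and 0.395. Gzmg had a ratio of 0.255, with 88.1% of its IgG UMIs and 53.8% of its Ac UMIs in 1 cell each.

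Among the gene lists in Ac against IgG, the 31 measured genes of G2 and M phase had a median ratio of 1.22, at percentile 100 of 10000 random lists of matched expression. Hmmr and Ccnb1, which act in mitosis, were 1.34 and 1.32 times higher, while the 24 S phase genes had a median of 0.887 (percentile 0), with the DNA replication gene Mcm2 at 0.711; no member of either list reached 1.5 times. The 28 genes of the type I interferon response had a median of 1.13 (percentile 100), with 1 at least 1.5 times higher, Rtp4 at 1.51, and 2 lower. The medians were 1.14 for glycolysis, 1.12 for hypoxia, 1.17 for cholesterol biosynthesis, 1.04 for exhaustion and inhibitory receptors, 1.04 for interferon gamma response and MHC class I, and 1.05 for cytotoxic effectors. Of these, the interferon gamma list was at 0.956 with cells of at least 500 UMIs, 0.978 at a mitochondrial maximum of 5% and 0.961 at a Leiden resolution of 0.5. The cytotoxic list was at 0.987 without sub-cluster 6, a group of cells almost wholly from Ac; this setting too was chosen after seeing the data. The medians were 0.908 for the unfolded protein response, 0.927 for immediate early and dissociation genes and 0.875 for mitochondrially encoded genes. Among the inhibitory receptors of the exhaustion list, Pdcd1 had a ratio of 1.13, Havcr2 1.08, Ctla4 1.02 and Lag3 1.02.

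The remaining lists lay within the middle 95% of random lists in Ac against IgG: naive, memory and stem-like at 0.930, tissue residency at 0.982, T cell activation and costimulation at 1.04, cytokines and chemokines of T cells at 1.02, MHC class II at 1.01, oxidative phosphorylation at 0.999, amino acid response at 0.937, heat shock at 0.940, TNF and NF-kB response at 0.999, TGF-beta response at 1.03, p53 response at 0.983 and ribosomal proteins at 1.01. Macrophage genes were also counted in the CD8 T-like cells: the alternative macrophage list had a median of 2.83 over 8 members and the inflammatory macrophage list one of 1.29 over 8, of which Ccl5 is a T cell gene too. The inflammatory median was 0.951 with cells of at least 500 UMIs, 0.753 at a mitochondrial maximum of 20%, 0.797 with doublets kept and 0.734 at a Leiden resolution of 0.5. Cells with at least 5 UMIs of macrophage markers made up 3.60% of the class in Ac and 1.15% in IgG. Without sub-clusters 8 and 11, 20 genes were at least 2 times higher and 7 lower.

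**Figure D2:**
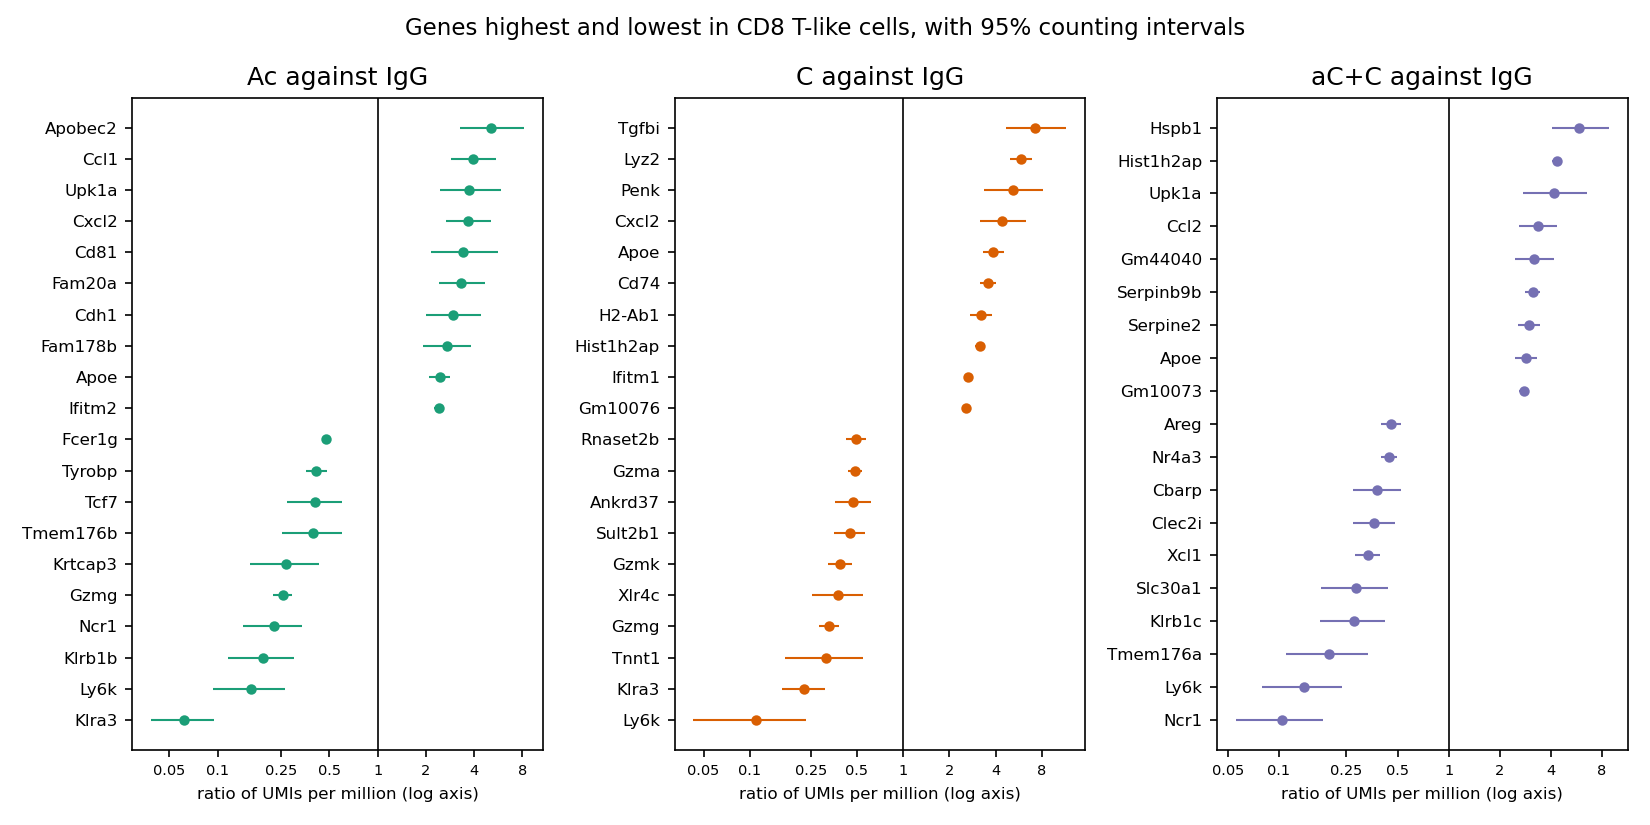
Ratio of CPM (horizontal log axis) with exact 95% intervals for counting error in CD8 T-like cells, for the 10 highest (9 for aC+C) and 10 lowest genes of Ac, C and aC+C, each against IgG (1 library per group). Klra3 lay at 0.0621 in Ac, Tgfbi at 7.22 in C and Serpinb9b at 3.12 in aC+C.

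C was compared with IgG in the same way, and 38 of 8230 genes were at least 2 times higher and 17 at least 2 times lower in its CD8 T-like cells. These counts were 59 and 13 when cells were taken by transcripts, 57 and 14 at a Leiden resolution of 0.5, and 27 and 18 with 5% background removed. Ifng (ENSMUSG00000055170), which encodes interferon gamma, was 1.75 times higher (1.66 to 1.85), with 398 against 228 CPM. Xcl1, a chemokine that attracts cross-presenting dendritic cells, was 2.03 times higher (1.81 to 2.27), Ccl3 1.61 times (1.49 to 1.73) and Tnf 1.54 times (1.14 to 2.07). The cytokine list had a median of 1.39 over 13 members (percentile 100), of which 5 were at least 1.5 times higher and 0 lower. Granzyme genes went both ways: Gzmk had a ratio of 0.387 (0.321 to 0.464), Gzma 0.483, Gzmb 0.787 (0.768 to 0.807) and Gzmf 1.43, and Prf1 was 1.24 times higher. Gzma was 1.71 times higher with cells of at least 500 UMIs, 1.27 times at a Leiden resolution of 0.5 and 1.13 times when cells were taken by their Cd8a or Cd8b1 transcripts. Gzmg had a ratio of 0.330, with 88.1% of its IgG UMIs and 48.0% of its C UMIs in 1 cell each. Pdcd1 had a ratio of 0.740 (0.697 to 0.785), with 246 against 333 CPM, and Cd274, which encodes its ligand PD-L1, 0.668.

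Transcripts of antigen-presenting cells were higher in the CD8 T-like cells of C than of IgG. All 8 measured MHC class II genes, which present antigen to CD4 T cells, were at least 1.5 times higher, with a median of 2.53 (percentile 100); Cd74 was 3.56 times higher (3.15 to 4.03) and H2-Ab1 3.21 times (2.72 to 3.79). The median was 1.36 with doublets kept and 1.37 at a mitochondrial maximum of 20%. Lyz2 was 5.84 times higher, Tgfbi 7.22 times, Apoe 3.86 times and Cxcl2 4.41 times, all genes of myeloid cells, and the alternative macrophage list had a median of 3.81 over 8 members. In C, 36.3% of the Lyz2 UMIs were in 1 cell, as were 48.8% of those of Penk, which was 5.15 times higher. Cells with at least 5 UMIs of macrophage markers made up 10.4% of the class in C and 1.15% in IgG, and sub-cluster 11, led by myeloid genes, 2.99% and 0.492%. Without sub-clusters 8 and 11, Lyz2 was 2.28 times and Cd74 2.23 times higher, and 27 genes were at least 2 times higher and 19 lower.

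Among the other lists in C against IgG, naive, memory and stem-like genes had a median of 1.23, with the migration regulator Klf2 at 1.57 and Tcf7 at 1.43 (1.04 to 1.96). Tissue residency genes had a median of 1.31, G2 and M phase 1.245, TNF and NF-kB response 1.21, immediate early and dissociation genes 1.15, cholesterol biosynthesis 1.12 and ribosomal proteins 1.05. Of the immediate early genes, which respond to stimulation and to tissue dissociation, 4 of 16 were at least 1.5 times higher, among them Atf3 at 2.03 and Fos at 1.53. The medians were 0.892 for cytotoxic effectors, 0.895 for exhaustion and inhibitory receptors, 0.851 for the type I interferon response, 0.950 for interferon gamma response and MHC class I, 0.932 for S phase, 0.925 for hypoxia, 0.938 for oxidative phosphorylation and 0.922 for heat shock. Isg15 and Rsad2, both antiviral interferon-stimulated genes, had ratios of 0.680 and 0.605. Both are among the leading genes of sub-cluster 4, named interferon response-like. It made up 5.67% of the class in C (3.45 to 8.72) and 9.67% in IgG (7.44 to 12.3). These 2 ratios therefore do not separate a change across the class from a change in its make-up. Lists in the middle 95% were activation at 0.996, glycolysis at 0.992, unfolded protein response at 0.986, amino acid response at 0.993, TGF-beta response at 1.00, p53 response at 1.08, inflammatory macrophage at 1.097 and mitochondrially encoded genes at 1.03. Klra3 had a ratio of 0.227 (0.162 to 0.310), Ly6k 0.109, Tnnt1 0.314, Xlr4c 0.378, Sult2b1 0.450, Rnaset2b 0.492 and Ankrd37, a hypoxia-responsive gene, 0.471. Ifitm1 was 2.64 times higher (2.47 to 2.82).

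Some genes high in C or aC+C were high in more than 1 class. Gm10076 was 2.56 times higher in C than in IgG in CD8 T-like cells, 2.55 times in NK-like cells, 2.77 times in monocyte or macrophage-like cells and 2.58 times in barcodes of 1 to 50 UMIs, which hold mainly free RNA. In aC+C its ratios were 2.32, 2.26, 2.35 and 2.08. Gm10073 had ratios of 2.32, 2.29, 2.63 and 2.30 in C and 2.78, 2.49, 2.81 and 2.60 in aC+C. The histone gene Hist1h2ap had ratios of 3.15, 3.07, 18.5 and 2.497 in C and 4.35, 4.32, 11.02 and 3.08 in aC+C; the values of 18.5 (8.88 to 46.5) and 11.02 (5.26 to 27.7) rest on 7 UMIs in the monocyte or macrophage-like cells of IgG. The glycolysis gene Pgk1 was 2.57 times higher in aC+C than in IgG in CD8 T-like cells, 2.56 times in NK-like cells and 2.80 times in monocyte or macrophage-like cells, and Eno1 1.75 times in CD8 T-like and 1.49 times in NK-like cells, with an interval of 1.18 to 1.32 in monocyte or macrophage-like cells. Apoe was 2.86 times higher in CD8 T-like, 2.95 times in NK-like and 1.13 times in monocyte or macrophage-like cells of aC+C.

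**Figure D3:**
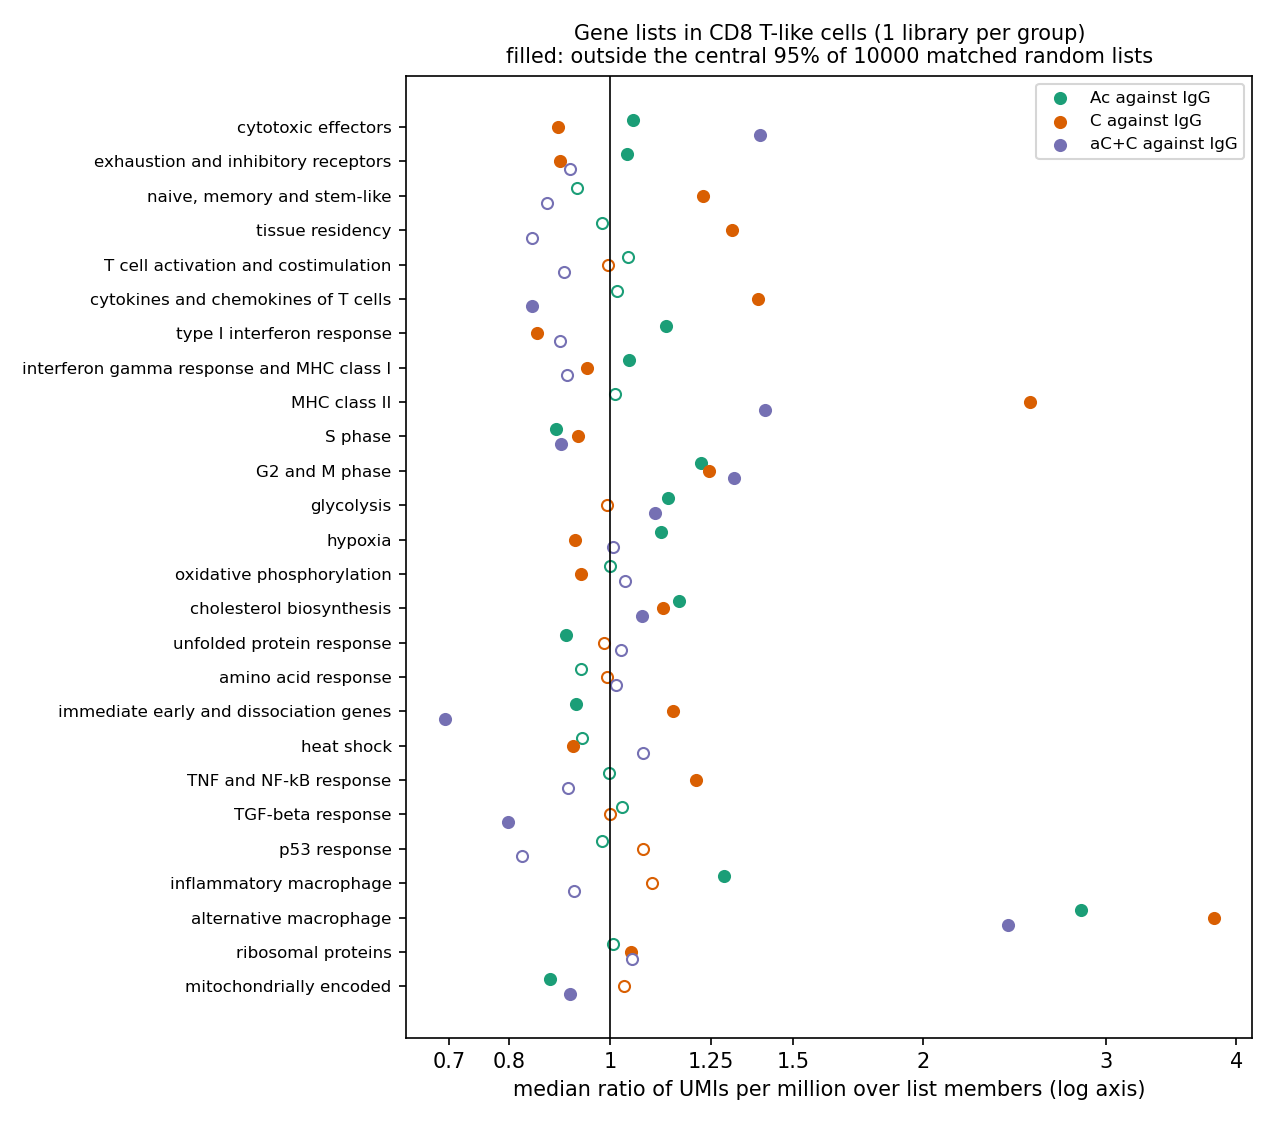
Median ratio over the measured members of each of 26 gene lists in CD8 T-like cells (horizontal log axis) for Ac, C and aC+C, each against IgG; filled points lie outside and open points inside the middle 95% of 10000 random lists of matched expression (1 library per group). The cytotoxic list lay at 0.892 in C and 1.39 in aC+C, and immediate early and dissociation genes at 1.15 in C and 0.694 in aC+C.

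In aC+C against IgG, 44 of 8615 genes were at least 2 times higher and 34 at least 2 times lower in CD8 T-like cells. These counts were 30 and 53 with 5% background removed, 43 and 49 at a Leiden resolution of 0.5, and 35 and 38 with doublets kept, so which side held more genes depended on the processing. Cytotoxic effectors were higher, with a median of 1.39 over 15 genes (percentile 100), of which 6 were at least 1.5 times higher and 1 lower. Sub-cluster 9, led by Gzmg, Gzmd, Gzme, Gzmf and Gzmc, made up 2.13% of the class in IgG, 2.55% in Ac, 4.78% in C and 8.65% in aC+C (6.53 to 11.2); since these genes are themselves on the list, its size is not separate evidence. Prf1 was 2.26 times higher (2.13 to 2.40), with 307 against 136 CPM, Gzmf 1.95 times (1.90 to 1.99) and Gzmb (ENSMUSG00000015437) 1.40 times (1.37 to 1.42). Gzmd and Gzme were 2.57 and 2.34 times higher, with 42.3% and 28.6% of their IgG UMIs in 1 cell. Serpinb9b, a relative of the inhibitor that shields killer cells from granzyme B, was 3.12 times higher (2.83 to 3.45). Prf1 and Serpinb9b are also among the leading genes of sub-cluster 9. The cytotoxic values therefore do not separate a change across the class from a change in its make-up. This also holds for aC+C against Ac and against C. Ifng had a ratio of 0.964 (0.913 to 1.02), Ccl5 0.641 and Xcl1 0.334 (0.283 to 0.393); the Xcl1 ratio was 0.799 with cells of at least 500 UMIs, 0.558 at a Leiden resolution of 0.5 and 0.546 when cells were taken by transcripts. The cytokine list had a median of 0.841, with 3 of 12 members at least 1.5 times lower.

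Immediate early and dissociation genes, which respond to receptor signals and to tissue handling, had a median of 0.694 (percentile 0) in aC+C against IgG, with 5 of 15 at least 1.5 times lower and 1 higher; Nr4a1, which follows T cell receptor signalling, had a ratio of 0.485 (0.435 to 0.541), Fosb 0.530 and Egr1 0.608. The relatives Nr4a3 and Nr4a2, which are linked to T cell exhaustion, had ratios of 0.447 (0.400 to 0.499) and 0.502. The lower values were not confined to CD8 T-like cells: the list had a median of 0.717 in NK-like cells, with Nr4a1 at 0.401, Nr4a2 at 0.509, Nr4a3 at 0.598 and Fosb at 0.602, and 0.866 in monocyte or macrophage-like cells. The exhaustion list as a whole had a median of 0.916, inside the middle 95% of random lists, with Pdcd1 at 1.13, Havcr2 at 1.13, Ctla4 at 0.915, Lag3 at 0.949 and Tox, a transcription factor of exhausted cells, at 0.840. Tcf7 had a ratio of 0.509 (0.352 to 0.727) and Cd274 one of 0.627 (0.540 to 0.726). The Tcf7 value holds for this class only: with cells of at least 500 UMIs, a further T cell cluster with Lef1 and Tcf7 among its leading genes made up 4.53% of aC+C and 0.264% of IgG. TGF-beta response genes had a median of 0.799, S phase genes 0.897 and mitochondrially encoded genes 0.916. The cell division genes of G2 and M phase were higher, with a median of 1.32 (percentile 100), 5 of 31 at least 1.5 times higher and Ube2c at 1.62. Cycling sub-cluster 3, led by Ube2c and Cenpf, made up 10.2% of the class in IgG, 13.2% in Ac, 12.2% in C and 19.3% in aC+C, and since such genes define it, its size is not separate evidence. Glycolysis genes had a median of 1.105, with Pgk1 at 2.57 and Eno1 at 1.75, against 1.095 in NK-like and 1.07 in monocyte or macrophage-like cells.

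The extremes of aC+C against IgG also included lipid, chaperone and NK cell genes. Apoe was 2.86 times higher, Ccl2, a monocyte-attracting chemokine, 3.34 times, Serpine2 2.96 times, Upk1a 4.17 times, Gm44040 3.19 times and the small chaperone Hspb1 5.88 times, with 48.5% of the IgG UMIs of Hspb1 in 1 cell. Ncr1 had a ratio of 0.105 (0.0557 to 0.182), Klrb1c 0.276, Clec2i 0.365, Tmem176a 0.198, Ly6k 0.140, the zinc transporter Slc30a1 0.283, Cbarp 0.381 and the growth factor gene Areg 0.458. Sub-cluster 8, led by NK cell genes, made up 2.995% of the class in aC+C and 8.03% in IgG, and without sub-clusters 8 and 11, 37 genes were at least 2 times higher and 21 lower. The MHC class II list had a median of 1.41, but 0.999 with cells of at least 500 UMIs, 0.878 with cells of at least 1000, 0.707 at a mitochondrial maximum of 5%, 0.693 at one of 20%, 0.574 with doublets kept and 0.669 at a Leiden resolution of 0.5. The alternative macrophage list had a median of 2.41, where cells with at least 5 UMIs of macrophage markers made up 5.99% in aC+C and 1.15% in IgG. Cholesterol biosynthesis had a median of 1.07, but 0.986 at a Leiden resolution of 0.5 and 0.988 for genes with at least 300 UMIs. Inside the middle 95% were naive, memory and stem-like genes at 0.871, tissue residency at 0.841, activation at 0.904, type I interferon at 0.894, interferon gamma and MHC class I at 0.909, hypoxia at 1.01, oxidative phosphorylation at 1.03, unfolded protein response at 1.03, amino acid response at 1.01, heat shock at 1.08, TNF and NF-kB response at 0.911, p53 response at 0.823, inflammatory macrophage at 0.924 and ribosomal proteins at 1.05.

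The other genes fixed in advance had these ratios in CD8 T-like cells of Ac, C and aC+C, each against IgG. Cd8b1 had 0.996, 0.879 and 0.916, Cd3e 1.04, 0.872 and 0.872, Ptprc 0.993, 0.946 and 0.783, and Mki67, a marker of dividing cells, 1.197, 1.28 and 1.11. Genes with fewer than 100 UMIs in each library were Tigit at 1.17, 1.504 and 1.21, Cd4 at 0.832, 1.44 and 0.664 and Epcam at 0.551, 1.07 and 0.633. Cd8a had 0.902 in C and 0.978 in aC+C. In C, Ctla4 had 0.843, Lag3 0.868, Havcr2 1.04 and Tox 1.07. In Ac, Tox had 1.06, Ifng 0.945 and Cd274 0.913. Muc2 had at most 1 UMI in the class of any library, so no ratio is given.

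For aC+C against Ac, 30 of 8622 genes were at least 2 times higher and 37 at least 2 times lower in CD8 T-like cells. Cytotoxic effectors had a median of 1.16 over 15 genes, with 6 at least 1.5 times higher and 0 lower; Gzme was 3.75 times higher (3.52 to 4.001), Gzmd 3.61 times, Gzmc 2.63 times, Prf1 1.65 times (1.56 to 1.74) and Gzmb 1.32 times. Gzmg was 6.48 times higher, with 53.8% of its Ac UMIs in 1 cell, and Klra3 14.9 times (9.68 to 24.1). Ccl5 was lower, with a ratio of 0.423 (0.412 to 0.433), as was Xcl1 at 0.423. Ccl5 is a leading gene of sub-cluster 6, which held 148 of 667 cells of Ac and 4 of 601 of aC+C. Its ratio therefore does not separate a change across the class from a change in its make-up. The TGF-beta response list had a median of 0.767, with 5 of 13 genes at least 1.5 times lower, among them Pmepa1 at 0.437 (0.390 to 0.489) and Smad7 at 0.652, both feedback inhibitors of that pathway. Tissue residency had a median of 0.706, immediate early and dissociation genes 0.762, the type I interferon response 0.810, cytokines 0.849, TNF and NF-kB response 0.870 and interferon gamma response and MHC class I 0.892. Pdcd1 had a ratio of 1.00 (0.958 to 1.04), Ifng 1.02, Tox 0.794 and Cd274 0.686.

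Further lists in aC+C against Ac were higher: MHC class II at 1.37, the unfolded protein response at 1.13, heat shock at 1.17, S phase at 1.07 and G2 and M phase at 1.09. The last 2 medians were 0.951 and 0.931 without sub-cluster 6, and without it 24 genes rather than 37 were at least 2 times lower. The inflammatory macrophage list had a median of 1.18, but 0.516 after removal of 5% background and 0.840 with genes of at least 30 UMIs. Apobec2, with a ratio of 0.0872 (0.0424 to 0.162), Ccl1 at 0.230, Cdh1 at 0.246, Lilr4b at 0.271 and Areg at 0.299 were the lowest genes. Hist1h2ap had a ratio of 3.74.

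For aC+C against C, 20 of 8189 genes were at least 2 times higher and 45 at least 2 times lower in CD8 T-like cells. The counts were 26 and 98 at a Leiden resolution of 0.5, 21 and 71 with cells of at least 500 UMIs, 23 and 75 when cells were taken by transcripts, 19 and 27 without sub-clusters 8 and 11, and 28 and 26 with totals scaled by TMM. Cytotoxic effectors had a median of 1.53 over 15 genes (percentile 100), with 8 at least 1.5 times higher and 0 lower; Gzmk was 3.14 times higher (2.63 to 3.77), Gzmd 2.88 times (2.72 to 3.05), Prf1 1.82 times (1.70 to 1.95) and Gzmb 1.77 times (1.73 to 1.82). Cytokine genes were lower, with a median of 0.629 and 7 of 13 at least 1.5 times lower: Xcl1 had a ratio of 0.165 (0.140 to 0.193), Ccl4 0.523, Ifng 0.551 (0.521 to 0.582) and Tnf 0.566. The Xcl1 ratio was 0.423 with cells of at least 500 UMIs and 0.340 at a Leiden resolution of 0.5. Immediate early and dissociation genes had a median of 0.643, with 9 of 16 at least 1.5 times lower, among them Fos at 0.454 and Zfp36, which destabilises cytokine transcripts, at 0.472. Naive, memory and stem-like genes had a median of 0.739, with 8 of 16 at least 1.5 times lower and Tcf7 at 0.356 (0.242 to 0.518). These values hold for this class only. With cells of at least 500 UMIs, the further T cell cluster led by Lef1 and Tcf7 made up 4.53% of aC+C and 0.454% of C. Pdcd1 was 1.53 times higher (1.44 to 1.62), Upk1a 10.7 times (4.77 to 29.7), Klra3 4.08 times and Gm44040 4.46 times, and Gzmg 5.01 times with 48.0% of its C UMIs in 1 cell.

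The other lists in aC+C against C included MHC class II at 0.536, tissue residency at 0.672, TNF and NF-kB response at 0.745, inflammatory macrophage at 0.751 and TGF-beta response at 0.837. Higher medians were 1.18 for hypoxia, 1.14 for glycolysis, 1.09 for oxidative phosphorylation, 1.06 for the amino acid response and 1.08 for heat shock. The exhaustion list had a median of 1.06, but 0.994 with cells of at least 500 UMIs, 0.947 at a Leiden resolution of 0.5 and 0.930 when cells were taken by transcripts. The type I interferon median of 1.06 was 0.980, 0.946 and 0.938 under the same settings, and the G2 and M phase median of 1.07 was 0.977 at a mitochondrial maximum of 5% and 0.994 at a Leiden resolution of 0.5. Among the lowest genes were Klrb1a at 0.218, Clec2i at 0.286, Tyrobp at 0.360 and Tmem176b at 0.192; sub-cluster 8 made up 2.995% of the class in aC+C and 9.55% in C.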

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

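The tests with macrophage markers alone, all tests of cluster 9, and those of UMI depth and of cell state in sub-cluster 6 were chosen only after the result was seen.

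In aC+C against IgG, 2 list medians were at most 0.8 in another class and at least the inverse of 0.8 in CD8 T-like cells, 1 of them for 2 other classes; the differences between classes were not tested. Cytotoxic effectors had a median ratio of 1.39 in CD8 T-like cells and 0.259 in monocyte or macrophage-like cells. The latter class served above as background for Prf1, and the NK-like share was lower in aC+C than in IgG. The value of 0.259 may thus come from transcripts of other cells, which was not tested. In NK-like cells the median was 1.05, inside the middle 95% of random lists, with Prf1 at 1.47. MHC class II genes had a median of 1.41 in CD8 T-like cells, 0.342 in NK-like cells and 0.672 in monocyte or macrophage-like cells. The median of 1.41 did not hold across the processing: it was 0.999 with cells of at least 500 UMIs, 0.878 with at least 1000, 0.707 and 0.693 at mitochondrial maximums of 5% and 20%, 0.574 with doublets kept and 0.669 at Leiden 0.5. In NK-like cells of IgG, 36.1% of the H2-Aa UMIs and 35.0% of the H2-Ab1 UMIs lay in 1 cell.

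Taking cells of at least 500 UMIs adds barcodes that the comparisons of the report leave out except as an alternative, and these brought in 2 groups of cells that had no class of their own over the threshold. B-like cells made up 1.72% of aC+C (70 of 4061 cells, 1.35 to 2.17) and 0.293% of IgG (10 of 3410 cells), with a median of 3464.5 UMIs. A T cell cluster led by Lef1, a transcription factor of naive T cells, made up 4.53% of aC+C (184 of 4061 cells, 3.91 to 5.22) and 0.264% of IgG (9 of 3410 cells), with a median of 3794.5 UMIs.

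MHC class II transcripts were higher in the CD8 T-like cells of C than of IgG, with a median ratio of 2.53. Free RNA spread evenly over all droplets would leave under 20% of these UMIs in the 5% of cells with the most, and 63.0% were there in C, which argues against free RNA as the whole source; IgG itself had 47.0%, and the MHC class II UMIs of the other cells still came to 114 CPM of the class total in C against 55.9 in IgG, so free RNA may account for a part. Droplets with a CD8 T cell and a myeloid cell could not be tested as planned, because 92.2% of the class in C had at least 5 macrophage or monocyte marker UMIs. The markers include Ly6c2 and Plac8, which CD8 T cells can express, but the UMIs were not split by marker. Without the cells holding at least 5 UMIs of macrophage markers alone, 10.4% of C and 1.15% of IgG, the median was 1.74 over 7 of the 8 genes, which argues against droplets shared with macrophages as the whole source, though the median over all cells was itself 1.36 with doublets kept and 1.37 at a mitochondrial maximum of 20%. Droplets shared with dendritic cells, and a state of the CD8 T cells that differs between the groups, were not tested and stay open.

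Cluster 9, whose cells carried T cell and myeloid transcripts together, made up 5.92% of IgG, 0.540% of Ac, 9.44% of C and 1.35% of aC+C. Droplets that held a T cell and a monocyte or macrophage by chance would follow a product. It is that of the cells called and the shares of T-like and monocyte or macrophage-like cells. This product was 2.17 times higher in Ac than in IgG. The share of cluster 9 in Ac was instead 0.0913 of that in IgG (0.0474 to 0.162). The share of 0.0913 argues against chance pairs of these cells. Chance pairs of T cells with dendritic cells, whose shares were lower in Ac than in IgG, were not tested. Free RNA of T cells would reach myeloid cells alike. With 8000 UMIs per cell, Cd3e was seen in 3.17% of monocyte or macrophage-like cells and 77.4% of cluster 9 in IgG. The ratio of these was 0.0410. But cluster 9 was picked out for its T cell transcripts, and clusters with Cd3e in most cells needed a higher score to be named. The ratio of 0.0410 thus follows at least in part from the sorting and cannot decide on free RNA. A cell state or cell pairing that differs between the groups is a candidate explanation, but with 1 library per group it cannot be told apart from a difference between single libraries.

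Sub-cluster 6 of the CD8 T-like cells held 148 of 667 cells of Ac, 8 of 610 of IgG, 1 of 335 of C and 4 of 601 of aC+C; its leading genes, among them Ly6c2 and Ccl5, also differ between the groups, so its size is not separate evidence. A difference between libraries that acts on every class would raise these genes in NK-like cells too, but their median ratio of Ac against IgG was 0.988 there. It was 0.732 in monocyte or macrophage-like cells. The 1.54 in CD8 T-like cells follows from choosing genes that lead a sub-cluster almost wholly from Ac, so it is not evidence. Droplets with a second cell would hold more UMIs, but the median was 10579.5 in sub-cluster 6 and 16192 in the other CD8 T-like cells of Ac, a ratio of 0.653. The ratio of 0.988 argues against a difference that acts on every class. The 0.653 rests partly on the cells compared, which include sub-clusters 2 and 3, with medians of 22565 and 23410 UMIs. Over all libraries, the lowest median of the other sub-clusters was 11394 UMIs in sub-cluster 1, against 10626 in sub-cluster 6. Sub-cluster 6 thus held no more UMIs than any other, which argues against a second cell of usual depth. Pairs of cells with few UMIs each were not tested. The state of these cells was not resolved, as the best score was 0.0461 for circulating effector cells with 2 markers detected, and with 1 library per group a state that differs between the groups cannot be told apart from a difference between single libraries.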

How the results depend on the processing

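Settings without sub-clusters 8 and 11, or without sub-cluster 6, were chosen only after the data were seen. Leaving out replicates was not possible because each group had 1 library, and no paired analysis was possible for the same reason. Over all settings, 1547 list medians moved by less than 1 SD of the random lists, 479 by more and 28 reversed. Of named genes, 2325 stayed inside the interval, 289 left it and 5 reversed. The 2325 include 169 and 132 at minimums of 30 and 300 UMIs per gene, which cannot change the ratio of a gene. Only lists outside the middle range of random lists, and genes at least 1.5 times higher or lower, could be called reversed. Other values that changed direction were counted with the rest. Counts of genes at least 2 times higher or lower stayed within 1.5 times in 126 cases and moved in 34, class shares stayed within their interval in 158 and moved in 62, and shares of cells with a UMI stayed in 23 and moved in 129, since they depend on the thinning depth. Of results that kept their direction under every setting, the median ratio of list cytotoxic effectors, aC+C against IgG, ranged from 1.23 to 1.47, and the Prf1 ratio, aC+C against IgG, from 2.19 to 2.39. The median ratio of list immediate early and dissociation genes, aC+C against IgG, ranged from 0.571 to 0.790, that of cytokines and chemokines of T cells, C against IgG, from 1.30 to 1.51, and the Ifng ratio, C against IgG, from 1.497 to 1.81. The NK-like share stayed lowest in aC+C. No setting left out sub-cluster 9, which Prf1 and several granzyme genes lead, so whether the cytotoxic values rest on it was not tested. Except where given below, the cause was not tested. Depth limits genes with few UMIs: a minimum of 30 or 300 UMIs changes how many genes are tested.

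Cells called were 3410 in IgG, 3972 in Ac, 4185 in C and 4061 in aC+C with at least 500 UMIs, 3342, 3897, 4066 and 3948 with at least 1000 UMIs, and 1928, 2210, 2142 and 2094 at a mitochondrial maximum of 5%, by construction of the filters. The CD8 T-like share was 22.2% of aC+C with at least 500 UMIs. With at least 1000 UMIs it was 24.1% of IgG, 12.2% of C and 20.7% of aC+C. At a mitochondrial maximum of 5% it was 29.7% of IgG, 31.7% of Ac and 28.8% of aC+C. At Leiden 0.5 it was 30.2% of IgG and 16.1% of C, and at Leiden 2 it was 29.4% of IgG and 31.0% of Ac. The NK-like share was 15.3% of IgG, 12.0% of Ac and 14.1% of C with at least 500 UMIs, 16.0%, 12.3% and 14.7% with at least 1000 UMIs, and 14.99% of C at a mitochondrial maximum of 5%. The monocyte or macrophage-like share was 16.0% of IgG, 27.3% of Ac and 29.1% of C with at least 500 UMIs, and 26.8% of Ac and 28.5% of C with at least 1000. In other classes, the fibroblast-like, regulatory T-like and migratory dendritic-like names were lost at Leiden 0.5, the regulatory T-like share of Ac was 9.49% with at least 500 UMIs, and the migratory dendritic-like share of IgG was 1.45% at a mitochondrial maximum of 5%.

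With genes of at least 30 UMIs, the counts of genes at least 2 times higher were 88 for Ac against IgG, 121 for C against IgG, 125 for aC+C against IgG, 80 for aC+C against Ac and 66 for aC+C against C, and those lower 78, 65, 134, 133 and 154. With genes of at least 300 UMIs they were 4, 18, 22, 15 and 10 higher and 4, 7, 7, 13 and 15 lower. Removal of 5% background gave 15 higher and 12 lower for Ac against IgG and 30 higher and 53 lower for aC+C against IgG. CD8 T-like cells taken by transcripts gave 59 higher for C against IgG and 75 lower for aC+C against C. For Ac against IgG, 16 were higher and 19 lower at a mitochondrial maximum of 20%, 18 and 20 with doublets kept, 17 and 26 at Leiden 0.5 and 20 and 7 without sub-clusters 8 and 11. For aC+C against C, 71 were lower with cells of at least 500 UMIs, 98 at Leiden 0.5, 26 with TMM and 27 without sub-clusters 8 and 11. Without sub-clusters 8 and 11, 37 were higher and 21 lower for aC+C against IgG, and without sub-cluster 6, 24 were lower for aC+C against Ac.

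Reversed values in CD8 T-like cells were these. With cells of at least 500 UMIs, Cd81 in Ac against IgG was 0.768, Gzma in C against IgG 1.71, MHC class II in aC+C against IgG 0.999, exhaustion in aC+C against C 0.994, inflammatory macrophage in Ac against IgG 0.951, interferon gamma in Ac against IgG 0.956 and type I interferon in aC+C against C 0.980. At Leiden 0.5 the same values were 0.938, 1.27, 0.669, 0.947, 0.734, 0.961 and 0.946, with G2 and M phase in aC+C against C at 0.994 and cholesterol biosynthesis in aC+C against IgG at 0.986. By transcripts, Gzma was 1.13, exhaustion 0.930 and type I interferon 0.938 in the same comparisons. MHC class II in aC+C against IgG was 0.878 with cells of at least 1000 UMIs, 0.707 and 0.693 at mitochondrial maximums of 5% and 20%, and 0.574 with doublets kept. Inflammatory macrophage in Ac against IgG was 0.753 at a mitochondrial maximum of 20% and 0.797 with doublets kept, and in aC+C against Ac it was 0.516 with 5% background removed and 0.840 with genes of at least 30 UMIs. At a mitochondrial maximum of 5%, interferon gamma in Ac against IgG was 0.978 and G2 and M phase in aC+C against C 0.977. Cholesterol biosynthesis in aC+C against IgG was 0.988 with genes of at least 300 UMIs. Without sub-cluster 6, G2 and M phase and S phase in aC+C against Ac were 0.931 and 0.951, and cytotoxic effectors in Ac against IgG 0.987.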

Other observations

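The values below were read off without tests. Monocyte or macrophage-like cells, which clear debris and present antigen, differed between the libraries in genes of cell division and inflammation. The G2 and M phase list had a median ratio of 2.63 in Ac against IgG, with 27 of 31 genes at least 1.5 times higher, and 2.03 in C and 1.92 in aC+C. The make-up of the class differed too: its cycling cluster 24 held 5 of 317 cells in IgG, 34 of 731 in Ac, 28 of 639 in C and 29 of 826 in aC+C, and cluster 12, led by Chil3 and Hp, 51, 84, 56 and 156, so these values do not separate changes within cells from changes in make-up. Nos2, which makes nitric oxide in inflammatory macrophages, was 4.58 times higher in Ac than in IgG and 8.20 times higher in aC+C, over only 27 UMIs in IgG. In aC+C against C, the inflammatory macrophage list had a median of 1.60, with 8 of 14 genes at least 1.5 times higher, among them Nos2 at 7.12 and Ccl5 at 2.97, and S phase genes one of 0.619. The type I interferon list had a median of 0.699 in Ac against IgG and 0.745 in C, and the interferon gamma list one of 1.41 in aC+C against Ac. Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, was 2.75 times higher in Ac, 4.60 times in C and 3.46 times in aC+C, over 19 UMIs in IgG with 47.4% in 1 cell, and Retnla, a marker of alternative activation, 16.9 times in C, with 36.3% of its C UMIs and 41.0% of its 39 IgG UMIs in 1 cell each. The neutrophil genes S100a9 and S100a8 were high in aC+C, but 98.1% and 94.1% of their UMIs lay in 1 cell.

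NK-like cells of aC+C, with 144 cells, had more transcripts of cell division than those of IgG: the G2 and M phase list had a median of 1.61, with 20 of 31 genes at least 1.5 times higher, Plk1 at 2.66 and Ube2c at 2.42. Ube2c had a UMI in 36 of the 144 cells and in 65 of 422 of IgG, and 18.4% of its aC+C UMIs lay in 1 cell. Here too, changes within cells are not separated from changes in make-up. The cytokine list of NK-like cells of aC+C had a median of 0.631 against C, with 7 of 12 genes at least 1.5 times lower and Ccl3 at 0.148. In the same comparison the MHC class II list had a median of 0.405, with Cd74 at 0.328. Of the C UMIs of H2-Aa, H2-Eb1 and Cd74, 28.5%, 35.6% and 17.4% lay in 1 cell each. The immediate early and dissociation list had a median of 0.722 against C, with Fos at 0.448. In C against IgG the cytokine list had a median of 1.27, with Ccl3 at 2.48 and Tnf at 2.27, of whose C UMIs 25% and 19.6% lay in 1 cell each. Both are genes of myeloid cells as well, and the myeloid genes Apoe and Fn1 were 4.33 and 5.12 times higher in the same comparison. The mast cell protease gene Mcpt2 had 440 UMIs in NK-like cells of C and 0 in those of IgG, but 99.8% of them lay in 1 cell. In regulatory T-like cells of C against IgG, the killer cell gene Gzma was 8.87 times higher (7.64 to 10.3). Of the IgG UMIs of Gzma, 39.2% lay in 1 cell. Most cells of this class also had a Cd8a UMI, as given above, and its name was lost at a lower Leiden resolution. The Gzma ratio therefore does not separate regulatory T cells from other cells in the class. Areg, a tissue repair factor, had a ratio of 0.385 (0.350 to 0.424) and the hypoxia list a median of 0.827. In regulatory T-like cells of Ac against IgG, Penk, which encodes an opioid peptide precursor, was 3.20 times higher (2.73 to 3.76). Fibroblast-like cells of aC+C had medians of 1.29 for the type I interferon list and 1.32 for the interferon gamma list against C, with Rsad2 at 2.58 and Cxcl10 at 2.68; the highest single genes of this class rest on few cells and are not given.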
